A study of Homo sapiens with 10 samples.

How the data were processed

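RNA-seq of PC3 human prostate cancer cells was analysed in 10 libraries, 2 in each of 5 groups named from the labels: Scramble shRNA, RNF2 shRNA1, RNF2 shRNA2, PRT4165 and GW-516. Per the labels' protocols, hairpins were stably expressed, compounds were applied for 48 hours, total RNA was extracted and stranded messenger RNA libraries were read from both ends. The deposited values are raw counts per gene, 1 table per library and with no normalization. Per the file headers, counting used featureCounts 1.4.3-p1 with the reverse-strand option 2 and GENCODE 18 genes. The recorded command has no option for read pairs, so each end of a fragment was counted; 62.7% to 69.6% of counts from 1 to 10 were even. Per the submitters' processing notes, the build was hg19 (GRCh37) and STAR (version not given in the sources used here) and DESeq2 1.8.1 were used, with no role stated.

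Counting both ends makes counts less independent than read fragments, which understates counting noise, while the spread between libraries used in the tests is measured from the values themselves. Genes with near-identical copies (AKR1C, histone, HLA, IFIT, keratin 6 and ribosomal protein genes) are uncertain, since the handling of reads that match several places is not given in the sources used here. Of 57445 gene identifiers 51812 (90.2%) matched a symbol in a table of GENCODE 29 names; coordinates are those of the count tables, on GRCh37. Total counts per library ran from 65877850 to 108380198. TMM factors ran from 0.972 to 1.05.

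The main test was edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr with a minimum count of 10, a model with 1 coefficient per group over all 10 libraries (5 residual degrees of freedom), robust quasi-likelihood F tests and two-sided p-values adjusted by Benjamini and Hochberg over 18478 genes in each of 9 comparisons. The common biological coefficient of variation was 0.0340, and the median prior degrees of freedom 18.6. A gene was called at an adjusted p below 0.05. Levels are TMM-normalized CPM. Comparisons set each hairpin group, the mean of both hairpin groups and each compound against Scramble, the hairpin groups and the compounds against each other, and each compound against the hairpin mean. With no vehicle group in the labels, comparisons of compounds with Scramble also hold effects of vehicle, hairpin vector and separate culture.

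The tests, groups, alternatives, gene lists and rule for named genes were fixed before the data were examined. The 28 lists were PRC1 subunits, PRC2 subunits, Polycomb target developmental regulators, chemokines and cytokines, NF-kB targets, interferon-stimulated genes, MHC class I antigen presentation, stemness genes, epithelial genes, mesenchymal genes, androgen receptor targets and luminal prostate genes, neuroendocrine genes, haematopoietic markers, stromal and endothelial markers, proliferation genes, cell cycle inhibitors and p53 targets, immediate early and AP-1 genes, integrated stress response, heat shock genes, NRF2 targets, AhR targets, PPAR targets, cholesterol synthesis, hypoxia and glycolysis, angiogenesis and invasion, replication-dependent histones, mitochondrially encoded genes and ribosomal proteins. They hold 852 entries, 14 of which matched no identifier. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 28 lists of a comparison, and again with an estimated correlation and with fry, which asks whether genes move 1 way on balance and does not compare a list with other genes. Of 252 tests over all comparisons 131 passed with the preset correlation and 78 with an estimated one. Member counts are over all genes tested, with the count adjusted over the list alone beside them. Named genes were RNF2, RING1, BMI1, EZH2, CCL2, CDKN1A, CDKN2A and ATF3 in every comparison; the 8 largest increases and 8 largest decreases among called genes with a symbol, a mean of at least 5 CPM in 1 of the groups and all libraries of 1 side above the other; and up to 4 members per list with the smallest adjusted p.

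Overlaps of calls were set against independent lists of the same sizes and against 30 draws of simulated unchanged groups sharing the Scramble libraries, once with the spread of the main fit and once with that of the fit with pairs summed; correlations and covariances used 13139 genes with a mean of at least 1 CPM. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 2 libraries, a fit of the groups compared alone, replicate number as a block, an adjusted p below 0.01, a change of at least 2-fold and each library left out. Added after seeing the data were the near-identical pairs of Scramble, RNF2 shRNA1 and GW-516 summed to 1 sample each (7 samples, 2 residual degrees of freedom), a fit without the libraries labelled RNF2 shRNA2 and counts thinned to the lowest total. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

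The steps were tested on simulated data, made with gene means pooled over all 10 libraries and with the sizes of those libraries. In the PRT4165 group 50 genes were changed at each of 4 folds, and PRT4165 was tested against Scramble over 17873 genes. Of these edgeR recovered 70% at 1.25-fold, 86% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and called 23 unchanged genes. With pairs summed (18422 genes) it recovered 62%, 86%, 98% and 100%, DESeq2 66%, 86%, 94% and 100%, and limma-voom 66%, 84%, 94% and 100%. These called 15, 14 and 15 unchanged genes in that order. In this simulation unchanged genes made up a larger share of each test's calls than the 0.05 threshold sets. In the list test a changed list gave a camera p of 1.4e-180, and of 100 unchanged lists none had a p below 0.05. Simulated genes varied independently, so this does not test lists whose genes vary together. Ribosomal proteins, for example, had an estimated correlation of 0.85 in PRT4165 against Scramble. Transcript isoforms, ligase activity and histone marks were not analysed here.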

Results

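RNA-seq was carried out on PC3, an established androgen receptor-low human prostate cancer cell line derived from a bone metastasis, in 5 groups of 2 libraries each. Per the labels, 6 libraries came from cells stably expressing a short hairpin RNA, either a Scramble control or 1 of 2 hairpins against RNF2. The other 4 came from cells treated for 48 hours with PRT4165 or GW-516. RNF2 is a ubiquitin ligase subunit of Polycomb repressive complex 1 (PRC1), which marks histone H2A on silenced genes. PRT4165 is known as an inhibitor of that ligase activity, and GW-516 is given in the labels by its code name alone. Per the file headers the GW-516 libraries carry the short name Th4, and whether that is the same compound is not stated in the labels. The study's title concerns how PRC1 relates to metastasis, stemness and immune suppression in prostate cancer lacking androgen receptor and neuroendocrine features. Total counts per library ran from 65877850 to 108380198, and 23340 to 25920 genes had at least 1 count. The labels give no dose and no vehicle-treated group, so both compounds were set against Scramble.

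Replicates differed little. Between the libraries of a pair, genes with at least 20 counts gave a chi-square per degree of freedom of 2.15 in Scramble, 2.19 in RNF2 shRNA1 and 2.20 in GW-516. The value was 12.2 in the libraries labelled RNF2 shRNA2 and 6.89 in PRT4165. Per the recorded command each end of a fragment was counted. Halving the values, as if every fragment had given 2 counts, lowered the 3 smallest to 1.08, 1.09 and 1.10, close to sampling noise. That assumption held only in part, since 62.7% to 69.6% of counts from 1 to 10 were even, so the halved values may be too low. The labels do not say that the libraries of a group came from separate cultures. Every edgeR p-value therefore measures only the spread between these samples, which may be technical. A camera p-value sets a list's genes against all other genes, so its size also reflects how many genes were compared. In RNF2 shRNA1 the camera adjusted p of cholesterol synthesis was 6.3e-93 with the preset correlation and 8.1e-05 with an estimated one. Each pair was kept as 2 libraries. Counts of called and shared genes over all genes tested are followed by those of a fit with the 3 near-identical pairs summed to 1 sample each. Calls of gene lists held with an estimated correlation unless that adjusted p is printed.

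The targeted gene went against the label of 1 hairpin group. RNF2 (ENSG00000121481.6, chromosome 1, 185014496 to 185071740, forward strand, GRCh37) stood at 29.5 ± 1.602 CPM (TMM-normalized counts scaled to library size, mean ± SD, n = 2) in Scramble. In RNF2 shRNA1 it stood at 12.02 ± 0.0807 CPM, 2.45-fold lower (log2 -1.29, SE 0.059, edgeR adjusted p = 2.3e-15). In the libraries labelled RNF2 shRNA2 it stood at 34.4 ± 1.248 CPM, 1.17-fold higher than in Scramble (log2 0.23, SE 0.052, edgeR adjusted p = 0.0010). BMI1 (ENSG00000168283.9, chromosome 10, 22610140 to 22620413, forward strand, GRCh37) encodes a subunit that pairs with RNF2 in canonical PRC1. It fell instead in those libraries, from 253 ± 2.296 to 57.3 ± 6.07 CPM, 4.402-fold (log2 -2.14, SE 0.054, edgeR adjusted p = 9.8e-12). Every direction drawn from the libraries labelled RNF2 shRNA2, alone or in a mean of both hairpins, therefore comes from cells in which BMI1 mRNA was reduced and RNF2 mRNA was not.

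Neither compound moved RNF2 mRNA past the threshold. It stood at 29.1 ± 0.0477 CPM with PRT4165 (log2 -0.018, 95% interval -0.13 to 0.092, edgeR adjusted p = 0.82) and 27.5 ± 0.846 with GW-516 (log2 -0.102, 95% interval -0.21 to 0.0077, edgeR adjusted p = 0.11). BMI1 stood at 251 ± 7.91 CPM with PRT4165 (log2 -0.012, 95% interval -0.12 to 0.097). In RNF2 shRNA1 BMI1 stood at 231 ± 1.23 CPM (log2 -0.13, edgeR adjusted p = 0.042). That call was lost with RLE size factors (edgeR adjusted p = 0.0896) and with pairs summed (0.329). It was lost, too, without RNF2 shRNA1 replicate 1 (edgeR adjusted p = 0.112) or 2 (0.236) and without Scramble replicate 1 (0.146) or 2 (0.238). With GW-516 BMI1 stood at 223 ± 2.48 CPM (log2 -0.18, edgeR adjusted p = 0.0076). This call was lost without Scramble replicate 2 (edgeR adjusted p = 0.0784), without GW-516 replicate 1 (0.0826) and with pairs summed (0.123).

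**Figure D1:**
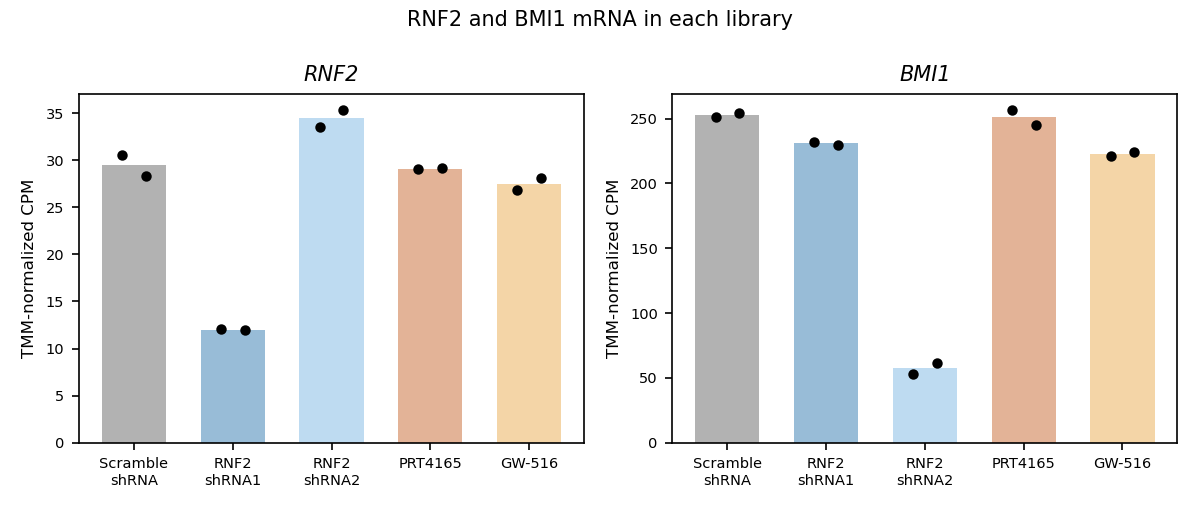
Bars show the mean and dots each of 2 libraries per group for RNF2 (left) and BMI1 (right), in TMM-normalized CPM on axes that start at 0. RNF2 was low in RNF2 shRNA1 (mean 12.02 CPM) and BMI1 in the libraries labelled RNF2 shRNA2 (mean 57.3 CPM).

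The first hairpin against Scramble asked what changed when RNF2 mRNA was reduced. No other hairpin group had less RNF2, so effects of RNF2 loss cannot be told apart from other effects of this hairpin. INSIG1, a sterol-regulated protein that restrains sterol synthesis, rose 10.5-fold (log2 3.39, SE 0.041, n = 2 against 2). The sterol enzymes MSMO1 and HMGCS1 rose 6.74-fold and 6.31-fold (SE 0.037 and 0.033). The vasoactive peptide gene UTS2 rose 7.77-fold (log2 2.96, SE 0.11), and CHAC1, a glutathione-degrading enzyme of the stress response, 4.75-fold (log2 2.25, SE 0.088). CCL2 (ENSG00000108691.5, chromosome 17, 32582304 to 32584222, forward strand, GRCh37) encodes a chemokine that draws monocytes. It fell from 14.7 ± 0.0766 to 3.85 ± 0.657 CPM, 3.81-fold (log2 -1.93, SE 0.11, edgeR adjusted p = 3.3e-13). The siderophore-binding lipocalin LCN2 fell 12.6-fold (log2 -3.66, SE 0.063). The elastase inhibitor PI3 fell 8.203-fold, the adhesion molecule MCAM 7.97-fold and the complement component C3 4.94-fold (SE 0.13, 0.12 and 0.080).

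Of 24 cholesterol synthesis genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 6.3e-93). The integrated stress response, the ATF4 and unfolded protein programme, was higher as well. Among 36 of its genes tested, 28 rose and 5 fell (29 and 6 adjusted over the list alone, camera adjusted p = 1.6e-30). The asparagine synthetase ASNS stood at log2 1.66 and the leucine sensor SESN2 at 2.18 (SE 0.029 and 0.056). Of 48 proliferation genes, 14 rose and 31 fell (14 and 31 adjusted over the list alone, camera adjusted p = 6.4e-11). Among them the cell cycle transcription factor MYBL2 stood at -1.255 and the replicative helicase subunits MCM3 and MCM4 at -0.82 and -0.89. Of 36 cell cycle inhibitors and p53 targets, 18 rose and 9 fell (18 and 9 adjusted over the list alone, camera adjusted p = 7.6e-06), the test pointing up. The pro-apoptotic PMAIP1 stood at 1.62, and CDKN1A, the inhibitor p21, rose 1.28-fold (log2 0.36, SE 0.062). Of 31 hypoxia and glycolysis genes, 4 rose and 24 fell (4 and 24 adjusted over the list alone, camera adjusted p = 4.6e-15). Lactate dehydrogenase LDHA stood at -0.898 and the glucose transporter SLC2A1 at -0.9996. Of 9 replication-dependent histones, 7 rose (7 adjusted over the list alone, camera adjusted p = 5.0e-06). Histone genes are near-identical copies, so their single values are uncertain. Of 13 mitochondrially encoded genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.81). With pairs summed 4 rose and 2 fell. The mitochondrial chromosome took 3.24% and 3.23% of counts in these libraries against 2.47% and 2.51% in Scramble. The mitochondrial ribosomal RNA MT-RNR2, named after its values were seen, took 1.297% and 1.29% of counts against 0.6399% and 0.6498%.

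Of 39 interferon-stimulated genes, 20 rose and 8 fell (20 and 8 adjusted over the list alone, camera adjusted p = 1.4e-04). DDX60 stood at log2 1.51 and OASL at 1.24. Of 10 aryl hydrocarbon receptor (AhR) targets, 5 rose (5 adjusted over the list alone, camera adjusted p = 1.7e-04). TIPARP stood at 0.92. Of 29 immediate early and AP-1 genes, 19 rose and 4 fell (19 and 4 adjusted over the list alone, camera adjusted p = 9.1e-08, adjusted p = 0.12 with an estimated correlation). They included ATF3, a stress-induced transcription factor (3.21-fold, log2 1.68, SE 0.054), and DUSP5 and SPRY2 (2.04 and 1.11), feedback inhibitors of MAP kinase signalling. Of 21 heat shock genes, 1 rose and 17 fell (1 and 17 adjusted over the list alone, camera adjusted p = 5.2e-04, adjusted p = 0.12 with an estimated correlation). With pairs summed 1 rose and 11 fell. Lists closest to PRC1 did not pass. Of 24 PRC1 subunits, 4 rose and 11 fell (4 and 11 adjusted over the list alone, camera adjusted p = 0.059). After RNF2, BCOR stood at -0.62 and L3MBTL2 at -0.66. Of 43 Polycomb target developmental regulators, 8 rose and 13 fell (8 and 13 adjusted over the list alone, camera adjusted p = 0.81). SOX21 stood at 1.83 and HOXB13 at -0.53. Chemokines and cytokines were mixed as well: among 28 of them, 10 rose and 8 fell (10 and 8 adjusted over the list alone, camera adjusted p = 0.81), with a median log2 of -0.035, a mean of -0.13 and a test pointing up. CXCL1, a neutrophil attractant, stood at -1.66 beside IL18 at 1.18. By edgeR 4834 genes were higher and 5278 lower, 801 and 782 of them by at least 2-fold. Adjusted p-values from edgeR reached at most 3.2e-06 among the 16 genes of largest change. With pairs summed 3449 were higher and 3528 lower, 582 and 596 by at least 2-fold, and 6957 of the 10112 calls were kept.

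In the libraries labelled RNF2 shRNA2, where RNF2 mRNA was not reduced, the growth factor genes FGF1 and FGF5 rose 3.58-fold and 2.57-fold against Scramble (SE 0.11 and 0.081, n = 2 against 2). FST, a secreted activin antagonist, rose 2.55-fold (log2 1.35, SE 0.046). The larger changes were downward. The serine protease gene TMPRSS15 fell 39.99-fold (log2 -5.32, SE 0.17) and the ubiquitin ligase gene TRIM31 28.6-fold (log2 -4.84, SE 0.12). LCN2 fell 14.04-fold and the membrane protein gene EMP2 10.1-fold (SE 0.061 and 0.15). CCL2 stood at 13.3 ± 0.283 CPM (log2 -0.14, 95% interval -0.34 to 0.053, edgeR adjusted p = 0.25). Of 18 MHC class I antigen presentation genes, 2 rose and 10 fell (2 and 10 adjusted over the list alone, camera adjusted p = 3.6e-04, adjusted p = 0.12 with an estimated correlation). The immunoproteasome subunits PSMB9 and PSMB8 stood at -2.23 and -1.36, and HLA-B, a gene with near-identical copies and so uncertain, at -1.55.

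Of 31 mesenchymal genes, 3 rose and 14 fell (3 and 14 adjusted over the list alone, camera adjusted p = 3.0e-05). The collagen COL6A2 stood at log2 -2.77, the cadherin CDH11 at -2.66 and, against the lean, the transcription factor SNAI2 at 0.93. Of 35 epithelial genes, 9 rose and 14 fell (10 and 15 adjusted over the list alone, camera adjusted p = 0.0076, adjusted p = 0.087 with an estimated correlation), the test pointing down. The junction proteins JUP and DSC2 stood at -1.59 and -0.97. The epithelial genes call was lost with no filter on low counts (camera adjusted p = 0.0970) and without RNF2 shRNA2 replicate 1 (camera adjusted p = 0.0523). Of 32 angiogenesis and invasion genes, 8 rose and 13 fell (9 and 13 adjusted over the list alone, camera adjusted p = 2.7e-05), with a median log2 of -0.081, a mean of 0.079 and a test pointing down. Those that moved included LCN2, the collagenase MMP13 (-1.53), TIMP2 (-0.81), which inhibits metalloproteinases, and ADAMTS1 (0.83). The angiogenesis and invasion call was lost with no filter on low counts (camera adjusted p = 0.0679). Of 48 proliferation genes, 27 fell (30 adjusted over the list alone, camera adjusted p = 1.1e-06). The mitotic kinases AURKA and CDK1 stood at -0.47 and -0.395. Of 36 integrated stress response genes, 22 rose and 8 fell (23 and 8 adjusted over the list alone, camera adjusted p = 3.3e-06). The pseudokinase TRIB3 stood at 0.82. Of 24 cholesterol synthesis genes, 17 rose and 3 fell (18 and 3 adjusted over the list alone, camera adjusted p = 4.4e-09). INSIG1 stood at 0.84. Of 9 histones, 7 rose (7 adjusted over the list alone, camera adjusted p = 3.2e-04).

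Of 29 immediate early and AP-1 genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone, camera adjusted p = 3.7e-05, adjusted p = 0.20 with an estimated correlation). MYC stood at log2 0.59, and ATF3 rose 1.74-fold (log2 0.796, SE 0.055). Of 13 mitochondrially encoded genes, 8 rose (8 adjusted over the list alone, camera adjusted p = 2.4e-04, adjusted p = 0.38 with an estimated correlation). Of 26 NF-kB targets, 6 rose and 13 fell (7 and 13 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.17 with an estimated correlation). The adhesion molecule ICAM1 stood at -0.59. The NF-kB targets call was lost without Scramble replicate 1 (camera adjusted p = 0.0523) and with the near-identical pairs summed (camera adjusted p = 0.0917). Of 24 PPAR targets, 3 rose and 10 fell (4 and 10 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.24 with an estimated correlation). The lipase inhibitor ANGPTL4 stood at -0.93. The PPAR targets call was lost without RNF2 shRNA2 replicate 2 (camera adjusted p = 0.0721). Stemness genes did not pass. Among 29 of them, 11 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.52). With pairs summed 6 rose and 4 fell. BMI1, itself a member, was lowest, and the integrin ITGA2 stood at 0.599. By edgeR 3895 genes were higher and 3877 lower, 305 and 594 of them by at least 2-fold. Adjusted p-values from edgeR reached at most 6.9e-10 among the 16 genes of largest change. With pairs summed 2206 were higher and 2696 lower, 187 and 519 by at least 2-fold, and 4880 of the 7772 calls were kept.

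Set directly against each other, the hairpin groups differed in RNF2, BMI1 and sterol genes. Against RNF2 shRNA1, the libraries labelled RNF2 shRNA2 had 2.87-fold more RNF2 (log2 1.52, SE 0.058, edgeR adjusted p = 5.1e-17, n = 2 against 2). They had 4.02-fold less BMI1 (log2 -2.01, SE 0.053, edgeR adjusted p = 4.5e-12) and 3.45-fold more CCL2 (log2 1.79, SE 0.11, edgeR adjusted p = 8.5e-13). ANGPT1, a ligand of the endothelial TEK receptor, was 20.8-fold higher and UTS2 34.9-fold lower (SE 0.18 and 0.14). Of 24 cholesterol synthesis genes, 2 were higher and 21 lower (2 and 21 adjusted over the list alone, camera adjusted p = 1.0e-49). Their median log2 was -1.04. Of 36 integrated stress response genes, 6 were higher and 28 lower (6 and 28 adjusted over the list alone, camera adjusted p = 7.5e-13). ASNS differed by -1.06. Of 31 hypoxia and glycolysis genes, 20 were higher and 4 lower (22 and 4 adjusted over the list alone, camera adjusted p = 3.0e-09). LDHA differed by 0.77. Of 31 mesenchymal genes, 6 were higher and 20 lower (6 and 20 adjusted over the list alone, camera adjusted p = 7.3e-04). CCN1, a secreted matricellular protein, differed by -2.49.

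CDKN2A, which encodes p16 and ARF, differed between the hairpin groups by log2 -0.61 (edgeR adjusted p = 0.036) and was not called in any comparison against Scramble. The difference was lost without RNF2 shRNA1 replicate 1 (edgeR adjusted p = 0.133) or 2 (0.0965), with replicate number as a block (0.0582) and with pairs summed (0.299). RING1, the paralogue of RNF2, differed by 0.22 (edgeR adjusted p = 0.015). It lost its call without RNF2 shRNA1 replicate 1 (edgeR adjusted p = 0.0604) or 2 (0.0882), without RNF2 shRNA2 replicate 1 (0.335) and with pairs summed (0.128). By edgeR 5534 genes were higher and 5401 lower in the libraries labelled RNF2 shRNA2, 893 and 1181 of them by at least 2-fold. Adjusted p-values from edgeR reached at most 1.1e-09 among the 16 genes of largest change. With pairs summed 4180 were higher and 4659 lower, 704 and 1078 by at least 2-fold, and 8786 of the 10935 calls were kept.

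The mean of both hairpins against Scramble, the knockdown effect as the design names it, mixes cells with less RNF2 and cells with less BMI1. LINC02015, a long non-coding RNA, was 20.6-fold lower (log2 -4.37, SE 0.12, n = 4 against 2), LCN2 13.3-fold (log2 -3.73, SE 0.048) and TRIM31 12.4-fold (log2 -3.63, SE 0.088). For each of these 3 genes the 4 hairpin libraries lay below both Scramble libraries. INSIG1 was 4.34-fold higher (log2 2.12, SE 0.037), RELN, a secreted matrix glycoprotein, 3.27-fold (log2 1.71, SE 0.062) and ATF3 2.36-fold (log2 1.24, SE 0.049). CCL2 was 2.05-fold lower by the mean (log2 -1.04, SE 0.086), from log2 -1.93 in RNF2 shRNA1 and -0.14, not called, in the libraries labelled RNF2 shRNA2. Among 48 proliferation genes, 3 rose and 36 fell (3 and 36 adjusted over the list alone, camera adjusted p = 6.8e-15). Of 36 integrated stress response genes, 28 rose and 6 fell (28 and 6 adjusted over the list alone, camera adjusted p = 4.6e-28). EZH2, the methyltransferase of PRC2, stood at log2 -0.32 in RNF2 shRNA1 (edgeR adjusted p = 2.4e-07, and 0.0022 with pairs summed). In the libraries labelled RNF2 shRNA2 it was not called (log2 0.086, edgeR adjusted p = 0.086). By the mean EZH2 stood at log2 -0.12 (edgeR adjusted p = 0.0068). It lost its call without Scramble replicate 1 (edgeR adjusted p = 0.0891) or 2 (0.0787), without RNF2 shRNA1 replicate 2 (0.0538) and with pairs summed (0.193). By edgeR 3964 genes were higher and 4520 lower, 290 and 507 of them by at least 2-fold. Adjusted p-values from edgeR reached at most 2.1e-06 among the 16 genes of largest change. With pairs summed 2279 were higher and 2793 lower, 187 and 377 by at least 2-fold, and 5054 of the 8484 calls were kept.

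PRT4165 against Scramble asked what followed a PRC1 ligase inhibitor, and also holds any effect of vehicle and of separate culture. The gel-forming mucins MUC5AC and MUC5B rose 27.5-fold and 13.6-fold (SE 0.15 and 0.054, n = 2 against 2). The inflammatory cytokine IL1B rose 10.4-fold (log2 3.38, SE 0.038), the chemokine CCL20 8.92-fold (log2 3.16, SE 0.16) and the fatty acid carrier FABP4 12.9-fold (log2 3.69, SE 0.044). CCL2 went the other way, from 14.7 ± 0.0766 to 4.89 ± 0.841 CPM, 2.99-fold lower (log2 -1.58, SE 0.105, edgeR adjusted p = 1.3e-11). The collagenases MMP13 and MMP1 fell 27.5-fold and 3.26-fold (SE 0.098 and 0.063). The mesenchymal cadherin CDH11 fell 10.8-fold (log2 -3.43, SE 0.21) and the heparin-binding growth factor PTN 4.95-fold (log2 -2.31, SE 0.14).

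Of 28 chemokines and cytokines, 16 rose and 6 fell (16 and 6 adjusted over the list alone, camera adjusted p = 3.6e-09). CXCL8 stood at log2 0.96 and LIF at 0.83. Of 35 epithelial genes, 21 rose and 4 fell (21 and 4 adjusted over the list alone, camera adjusted p = 1.1e-09). The integrin ITGB4 stood at 2.13 and E-cadherin, CDH1, at 1.401. Of 24 PPAR targets, 13 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 7.2e-13). The lipid droplet coat protein PLIN2 stood at 1.14 and PDK4 at 1.51. Of 31 hypoxia and glycolysis genes, 16 rose and 7 fell (17 and 8 adjusted over the list alone, camera adjusted p = 2.5e-05). NDRG1 stood at 1.45 and the vasodilator peptide ADM at 1.53. Of 29 stemness genes, 13 rose and 5 fell (13 and 5 adjusted over the list alone, camera adjusted p = 5.5e-04). The integrins ITGA2 and ITGA6 stood at 1.51 and 0.71. Of 39 interferon-stimulated genes, 10 rose and 21 fell (10 and 22 adjusted over the list alone, camera adjusted p = 2.4e-04). IFIT3 and IFIT1, related copies whose values are uncertain, stood at -0.98 and -0.798, and OAS1, against the lean, at 0.76. Of 48 proliferation genes, 4 rose and 32 fell (4 and 32 adjusted over the list alone, camera adjusted p = 1.7e-07). The thymidylate synthase TYMS stood at -0.49 and MCM2 at -0.44, while CDKN1A rose 1.92-fold (log2 0.94, SE 0.059).

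Further lists passed with the preset correlation alone. Of 11 PRC2 subunits, 2 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.12 with an estimated correlation). EZH2 stood at log2 -0.45 (SE 0.041). Of 28 NRF2 targets, 12 rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.083 with an estimated correlation). The transporter ABCC3 stood at 0.802 and AKR1C1, a gene with near-identical copies and so uncertain, at 2.49. Of 29 immediate early and AP-1 genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 2.5e-05, adjusted p = 0.16 with an estimated correlation). KLF6 stood at 1.16, the phosphatases DUSP6 and DUSP1, which damp MAP kinases, at 0.77 and 0.88, and ATF3 rose 1.19-fold (log2 0.25, SE 0.058). Of 24 cholesterol synthesis genes, 11 rose and 4 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.086 with an estimated correlation). Of 9 histones, 6 rose (6 adjusted over the list alone, camera adjusted p = 0.0028, adjusted p = 0.078 with an estimated correlation). Of 37 ribosomal proteins, 20 fell (22 adjusted over the list alone, camera adjusted p = 0.010, adjusted p = 0.66 with an estimated correlation). With pairs summed 5 fell. Under fry that list did not pass (fry adjusted p = 0.060). Of 21 heat shock genes, 2 rose and 14 fell (2 and 14 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.23 with an estimated correlation). With pairs summed 2 rose and 9 fell. The heat shock genes call was lost without PRT4165 replicate 2 (camera adjusted p = 0.0520). Of 13 mitochondrially encoded genes, 7 fell (1 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.48 with an estimated correlation). With pairs summed 1 rose and 5 fell. The mitochondrially encoded genes call was lost without PRT4165 replicate 2 (camera adjusted p = 0.0862). Polycomb target developmental regulators did not pass. Among 43 of them, 15 rose and 5 fell (15 and 9 adjusted over the list alone, camera adjusted p = 0.35). BMP2 stood at 0.97 and HOXB13 at -1.04. By edgeR 3681 genes were higher and 4014 lower, 598 and 282 of them by at least 2-fold. Adjusted p-values from edgeR reached at most 1.3e-11 among the 16 genes of largest change. With pairs summed 2553 were higher and 2358 lower, 477 and 212 by at least 2-fold, and 4896 of the 7695 calls were kept.

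GW-516 against Scramble asked what the other compound changed, under the limits given for PRT4165. The carboxypeptidase CPA4 rose 30.2-fold (log2 4.92, SE 0.076, n = 2 against 2) and the proton pump subunit ATP6V0A4 27.04-fold (log2 4.76, SE 0.21). MUC5AC rose 15.6-fold (log2 3.97, SE 0.15) and the water and glycerol channel AQP3 13.9-fold (log2 3.79, SE 0.17). AKR1C1 and the keratin KRT6A, both with near-identical copies and so uncertain, rose 38.4-fold and 15.9-fold (SE 0.15 and 0.15). CDKN1A rose from 15.3 ± 1.05 to 70.96 ± 1.99 CPM, 4.64-fold (log2 2.21, SE 0.057), and ATF3 3.17-fold (log2 1.67, SE 0.054). CCL2 fell to 4.78 ± 0.0555 CPM, 3.08-fold (log2 -1.62, SE 0.103, edgeR adjusted p = 2.7e-12). CDH11 fell 8.02-fold, PTN 7.74-fold and MMP13 6.96-fold (SE 0.200, 0.15 and 0.077).

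Of 48 proliferation genes, 1 rose and 47 fell (1 and 47 adjusted over the list alone, camera adjusted p = 9.2e-36). FOXM1, a mitotic transcription factor, stood at log2 -0.77 and cyclin B1, CCNB1, at -0.73. Of 9 histones, 9 rose (9 adjusted over the list alone, camera adjusted p = 2.2e-19). Their median log2 was 1.85, over copies that are uncertain singly. Of 28 NRF2 targets, the antioxidant programme, 24 rose and 1 fell (25 and 1 adjusted over the list alone, camera adjusted p = 3.5e-16). The haem oxygenase HMOX1 stood at 2.47 and NQO1 at 0.65. Of 29 immediate early and AP-1 genes, 24 rose and 2 fell (24 and 2 adjusted over the list alone, camera adjusted p = 2.6e-18). The feedback phosphatases DUSP1 and DUSP5 stood at 2.26 and 1.66. Of 28 chemokines and cytokines, 20 rose and 5 fell (21 and 5 adjusted over the list alone, camera adjusted p = 1.7e-11). IL1B stood at 2.31, CXCL8 at 1.799 and IL11 at 2.56. Of 35 epithelial genes, 24 rose and 6 fell (25 and 6 adjusted over the list alone, camera adjusted p = 8.0e-11). The laminin LAMB3 stood at 1.63 and ITGB4 at 1.94. Of 31 hypoxia and glycolysis genes, 24 rose and 5 fell (25 and 5 adjusted over the list alone, camera adjusted p = 5.1e-16). VEGFA stood at 0.87 and ADM at 2.26. Of 32 angiogenesis and invasion genes, 22 rose and 6 fell (23 and 6 adjusted over the list alone, camera adjusted p = 7.7e-08). TIMP1, an inhibitor of metalloproteinases, stood at 1.67, ANGPTL4 at 2.33 and the urokinase receptor PLAUR at 1.14, beside MMP13, which fell.

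Of 29 stemness genes, 17 rose and 5 fell (18 and 5 adjusted over the list alone, camera adjusted p = 7.1e-06). ITGA2 stood at log2 2.02, ID2 at 0.998 and the intermediate filament NES at -0.58. Of 36 cell cycle inhibitors and p53 targets, 18 rose and 8 fell (18 and 8 adjusted over the list alone, camera adjusted p = 7.2e-05). GADD45B stood at 1.44. Of 36 integrated stress response genes, 19 rose and 11 fell (20 and 12 adjusted over the list alone, camera adjusted p = 3.9e-05), the test pointing up. DDIT4 stood at 1.34. Of 10 AhR targets, 7 rose (7 adjusted over the list alone, camera adjusted p = 0.0031). The aldehyde dehydrogenase ALDH3A1 stood at 1.249. Of 24 cholesterol synthesis genes, 14 rose and 5 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.0035). Of 11 PRC2 subunits, 2 rose and 7 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.0080, adjusted p = 0.070 with an estimated correlation). PHF19 stood at -0.83 and EZH2 at -0.54 (SE 0.040). Of 37 ribosomal proteins, 29 fell (30 adjusted over the list alone, camera adjusted p = 3.3e-06, adjusted p = 0.45 with an estimated correlation). Of 13 mitochondrially encoded genes, 11 fell (12 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.23 with an estimated correlation). The mitochondrial chromosome took 2.25% and 2.26% of counts against 2.47% and 2.51% in Scramble. Of 31 mesenchymal genes, 18 rose and 6 fell (18 and 6 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.059 with an estimated correlation). Fibronectin, FN1, stood at 1.22 and the collagen COL5A2 at -0.97. Of 24 PPAR targets, 10 rose and 8 fell (10 and 8 adjusted over the list alone, camera adjusted p = 5.8e-04, adjusted p = 0.070 with an estimated correlation), the test pointing up. The PPAR targets call was lost with no filter on low counts (camera adjusted p = 0.0664).

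RING1 stood at log2 -0.18 with GW-516 (edgeR adjusted p = 0.040). That call was lost with RLE size factors (edgeR adjusted p = 0.0579), with DESeq2 (0.108) and with pairs summed (0.244). It was lost without Scramble replicate 1 (edgeR adjusted p = 0.0929) or 2 (0.224) and without GW-516 replicate 1 (0.247) or 2 (0.0888). Markers of other cell types did not pass as lists against Scramble in the fit of 10 libraries. Of 8 haematopoietic markers, 2 rose (2 adjusted over the list alone, camera adjusted p = 0.45). Of 11 stromal and endothelial markers, 7 rose (7 adjusted over the list alone, camera adjusted p = 0.059). With pairs summed the stromal and endothelial list passed (camera adjusted p = 0.024). Set against the hairpin mean, of 11 stromal and endothelial markers, 6 were higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.10 with an estimated correlation). The stromal and endothelial markers call was lost without RNF2 shRNA2 replicate 1 (camera adjusted p = 0.0528). By edgeR 4890 genes were higher and 5362 lower among 18478 tested with GW-516. Changes of at least 2-fold were mostly upward, 1414 against 258. The 16 genes of largest change had edgeR adjusted p-values of at most 3.3e-11. With pairs summed 3216 were higher and 3667 lower, 1078 and 172 by at least 2-fold, and 6837 of the 10252 calls were kept.

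**Figure D2:**
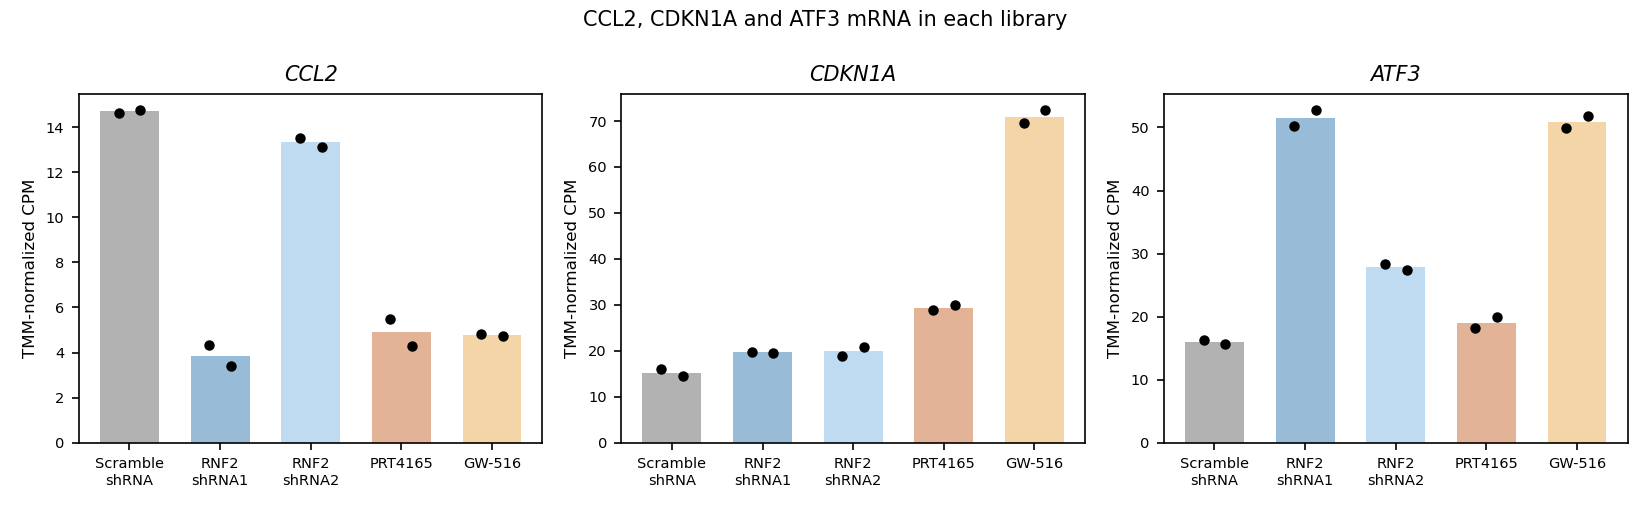
Bars show the mean and dots each of 2 libraries per group for CCL2, CDKN1A and ATF3, in TMM-normalized CPM on axes that start at 0. CCL2 averaged 3.85, 4.89 and 4.78 CPM in RNF2 shRNA1, PRT4165 and GW-516 against 14.7 in Scramble, and CDKN1A stood highest with GW-516 (70.96 CPM).

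The compounds were set directly against each other after 48 hours. Doses are not in the labels, so they cannot be called matched. CCL2 was not called different (log2 -0.041, 95% interval -0.27 to 0.19, edgeR adjusted p = 0.81). CDKN1A was 2.41-fold higher with GW-516 than with PRT4165 (log2 1.27, SE 0.053, n = 2 against 2). ATF3 was 2.67-fold higher (log2 1.42, SE 0.052) and FOS, an AP-1 subunit, 8.59-fold (log2 3.103, SE 0.13). The glycosyltransferase GCNT3 was 7.81-fold higher (log2 2.96, SE 0.21). FABP4 was 3.39-fold, MUC5B 2.22-fold and IL1B 2.095-fold lower with GW-516 (SE 0.039, 0.045 and 0.033).

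Of 48 proliferation genes, 2 were higher and 46 lower (2 and 46 adjusted over the list alone, camera adjusted p = 3.5e-38). MKI67, a marker of cycling cells, differed by log2 -0.85. Of 9 histones, 9 were higher (9 adjusted over the list alone, camera adjusted p = 1.7e-26). Their median log2 was 1.504. Of 28 NRF2 targets, 21 were higher and 2 lower (22 and 2 adjusted over the list alone, camera adjusted p = 6.6e-23). HMOX1 differed by 1.74. Of 29 immediate early and AP-1 genes, 18 were higher and 1 lower (19 and 1 adjusted over the list alone, camera adjusted p = 2.2e-17). Of 32 angiogenesis and invasion genes, 18 were higher and 3 lower (19 and 3 adjusted over the list alone, camera adjusted p = 1.3e-13). The inhibitor TIMP1 differed by 1.33 and the collagenase MMP1 by 1.97. Of 31 hypoxia and glycolysis genes, 22 were higher (23 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.4e-14). Of 36 integrated stress response genes, 25 were higher and 4 lower (26 and 4 adjusted over the list alone, camera adjusted p = 1.1e-12). DDIT3, a stress transcription factor, differed by 0.86. Of 39 interferon-stimulated genes, 17 were higher and 6 lower (17 and 6 adjusted over the list alone, camera adjusted p = 1.2e-04). Of 28 chemokines and cytokines, 12 were higher and 4 lower (13 and 4 adjusted over the list alone, camera adjusted p = 0.0020). CCL26 differed by 1.88. Of 24 PPAR targets, 1 was higher and 9 lower (1 and 9 adjusted over the list alone, camera adjusted p = 8.4e-04, adjusted p = 0.099 with an estimated correlation). CPT1A differed by -0.44 and ANGPTL4, against the lean, by 0.85.

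EZH2 was not called different between the compounds (log2 -0.0902, 95% interval -0.17 to -0.0059, edgeR adjusted p = 0.082), though it was without PRT4165 replicate 2 (edgeR adjusted p = 0.0197). BMI1 differed by log2 -0.17 (edgeR adjusted p = 0.015). It lost its call without PRT4165 replicate 1 (edgeR adjusted p = 0.230) or 2 (0.0833), without GW-516 replicate 1 (0.110) or 2 (0.0677) and with pairs summed (0.114). By edgeR 3348 genes were higher and 4246 lower with GW-516, 700 and 109 of them by at least 2-fold. Adjusted p-values from edgeR reached at most 7.4e-07 among the 16 genes of largest change. With pairs summed 1934 were higher and 2621 lower, 502 and 56 by at least 2-fold, and 4539 of the 7594 calls were kept.

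Each compound was also set against the mean of both hairpins, where Scramble drops out and the mix of RNF2 and BMI1 loss applies. LCN2 was 23.7-fold higher with PRT4165 and 18.5-fold with GW-516 (SE 0.047 and 0.047, n = 2 against 4). C15orf48 was 45.04-fold and 44.4-fold higher (SE 0.15 and 0.15). RELN was 6.18-fold lower with PRT4165 and 2.97-fold with GW-516 (SE 0.068 and 0.060). CDKN1A was 3.58-fold higher with GW-516 (log2 1.84, SE 0.044). Of 24 cholesterol synthesis genes, 2 were higher and 20 lower (2 and 20 adjusted over the list alone, camera adjusted p = 1.5e-36) with PRT4165. Of 24 such genes, 3 were higher and 20 lower (3 and 20 adjusted over the list alone, camera adjusted p = 6.9e-20) with GW-516. HMGCS1 differed by log2 -1.62 and -1.54. Of 31 hypoxia and glycolysis genes, 28 were higher (29 adjusted over the list alone, camera adjusted p = 1.1e-22) with PRT4165. With GW-516, of 31 such genes, 29 were higher (29 adjusted over the list alone, camera adjusted p = 1.8e-36). NDRG1 differed by 1.47 and 1.93. Of 35 epithelial genes, 19 were higher and 5 lower (21 and 5 adjusted over the list alone, camera adjusted p = 2.9e-12) with PRT4165. With GW-516, of 35 epithelial genes, 24 were higher and 4 lower (25 and 4 adjusted over the list alone, camera adjusted p = 1.8e-13). ITGB4 differed by 1.65 and 1.46. Among 48 proliferation genes, 4 were higher and 41 lower (4 and 42 adjusted over the list alone, camera adjusted p = 2.8e-11) with GW-516. With PRT4165 that list was not called: of 48 genes, 21 were higher and 8 lower (21 and 9 adjusted over the list alone, camera adjusted p = 0.19). By edgeR 9021 genes differed between PRT4165 and the hairpins, 875 higher and 278 lower by at least 2-fold, and with pairs summed 7333, 835 and 259. Between GW-516 and the hairpins 11366 differed, 1805 higher and 278 lower by at least 2-fold, and with pairs summed 8766, 1636 and 192.

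LCN2, EMP2 and TRIM31 fell and INSIG1 and ATF3 rose in both hairpin groups. By edgeR 1573 genes were higher and 1708 lower in both, where independent lists of those sizes give 1019 and 1107. Calls in opposite directions numbered 2196 (independent lists 2127). With pairs summed 1638 calls were shared in direction and 965 opposite. Simulated unchanged groups against the same Scramble libraries shared at most 2 calls over 30 draws, and at most 4 with the wider spread of the fit with pairs summed. Unchanged groups yield few calls of any kind. Here and below, the simulated counts of shared calls therefore cannot measure what shared controls add to long lists of calls. Across 13139 genes, which are not independent replicates, fold changes of the hairpin groups correlated at 0.262 (simulated 0.5105) with a covariance of 0.0537 (simulated 0.00502, or 0.00704 with the wider spread). Simulated unchanged groups correlate only because they share the Scramble libraries. Here and below, the simulated correlations are therefore no benchmark for groups that did change. The simulated covariance gives the size of that shared part under the simulated spread.

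MUC5AC, CPA4 and CDKN1A rose and CCL2, CDH11, MMP13 and PTN fell with both compounds. There 2675 genes were higher and 3155 lower in both by edgeR (independent lists 974 and 1165, simulated at most 2, or 3 with the wider spread). Opposite calls numbered 382 (independent lists 2130), and with pairs summed 3523 were shared in direction and 75 opposite. Fold changes of the compounds correlated at 0.768 (simulated 0.516) with a covariance of 0.152 (simulated 0.00506, or 0.00701 with the wider spread). Both compound groups may also differ from Scramble in vehicle, hairpin vector and culture. Changes shared for those reasons cannot be told apart here from a common response to the compounds.

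CCL2 was among the 2994 genes called in 1 direction in the hairpin mean and both compounds, a set of 1435 with pairs summed (independent lists 209 higher and 285 lower, simulated at most 1, or 2 with the wider spread). It was not called in the libraries labelled RNF2 shRNA2 (log2 -0.14, edgeR adjusted p = 0.25), so the next set leaves it out. In both hairpin groups and both compounds 1298 were called in 1 direction, and 556 with pairs summed (independent lists 53.7 and 69.8, simulated at most 1 with either spread). RNF2 shRNA1 alone shared 4208 calls in direction and 1403 opposite with PRT4165 (independent lists 963 higher, 1146 lower and 2102 opposite, 2332 and 571 with pairs summed). With GW-516 it shared 4562 calls in direction and 2324 opposite (independent lists 1279 higher, 1532 lower and 2800 opposite, 2544 and 1092 with pairs summed). Simulated groups with either spread shared at most 4 and 3 there, and the fold changes had covariances of 0.0541 and 0.049003 (simulated 0.004998 and 0.00501, or 0.00708 and 0.00706 with the wider spread). The libraries labelled RNF2 shRNA2 alone shared 2709 calls in direction and 1735 opposite with PRT4165 (independent lists 776 higher, 842 lower and 1618 opposite, 1350 and 730 with pairs summed). With GW-516 they shared 3242 calls in direction and 2276 opposite (independent lists 1031 higher, 1125 lower and 2156 opposite, 1639 and 929 with pairs summed). Simulated groups with either spread shared at most 4 and 3 there, and the fold changes had covariances of 0.0301 and 0.0348 (simulated 0.00507 and 0.00505, or 0.00696 and 0.00702 with the wider spread). The hairpin mean shared 3814 calls in direction with PRT4165 (independent lists 789.7 higher and 982 lower, simulated at most 2, or 4 with the wider spread, 1924 with pairs summed). It shared 4089 with GW-516 (independent lists 1049 and 1312, simulated at most 4, or 3 with the wider spread, 2054 with pairs summed). Opposite to the hairpin mean were 1173 calls of PRT4165 (independent lists 1762, 448 with pairs summed) and 1898 of GW-516 (independent lists 2346, 745 with pairs summed). The correlations were 0.299 and 0.227 (simulated 0.587 and 0.592). The covariances were 0.0421 and 0.0419 (simulated 0.00503 and 0.00503, or 0.00702 and 0.00704 with the wider spread). The 2 Scramble libraries served every comparison and were not divided between them, so part of each excess may come from the shared controls.

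**Figure D3:**
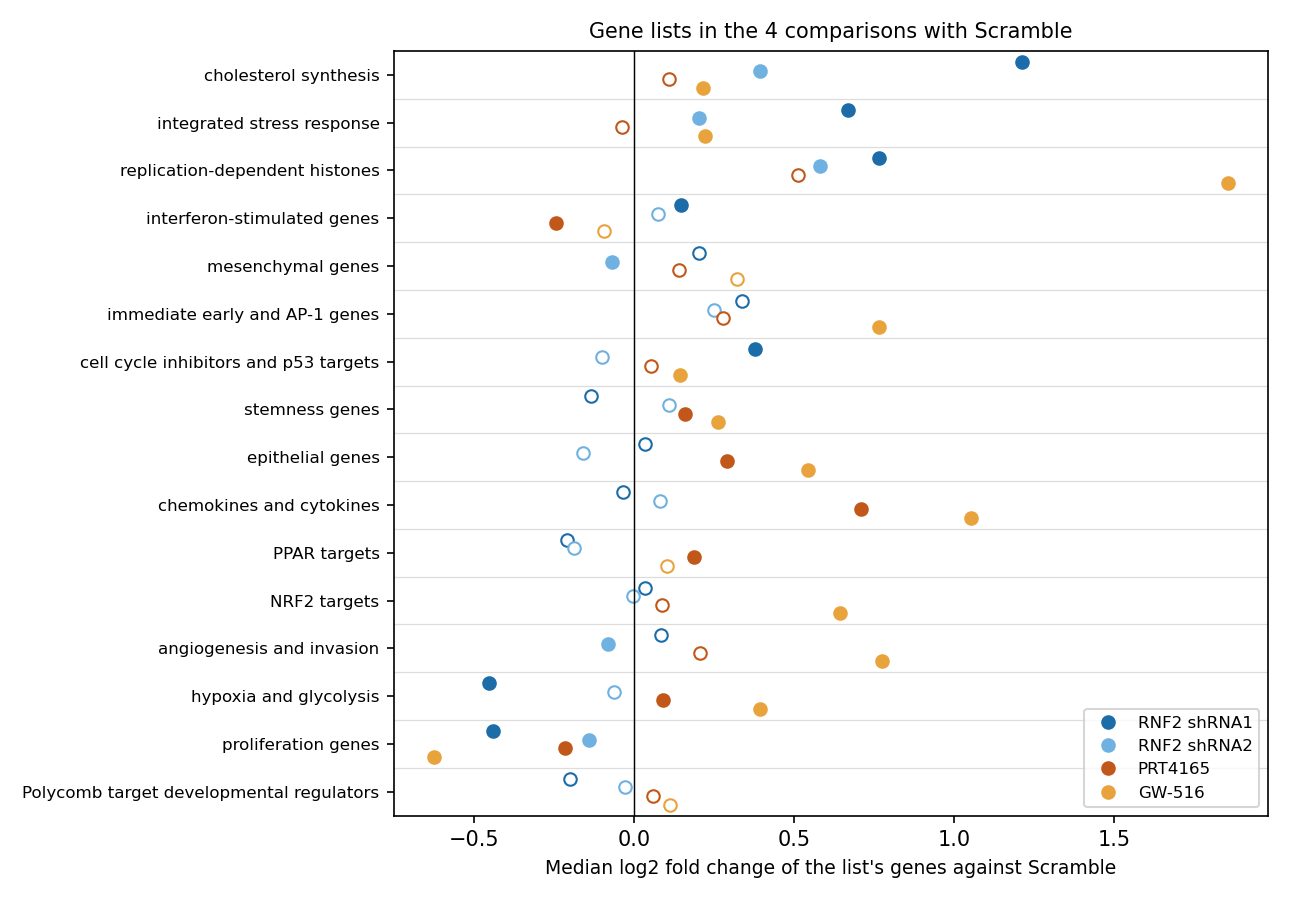
The horizontal axis gives the median log2 fold change against Scramble of the genes of 16 lists, in 4 comparisons marked by colour. Filled points passed the camera test with the preset and with an estimated correlation, and open points did not pass both; cholesterol synthesis in RNF2 shRNA1 lay at 1.21 and histones with GW-516 at 1.85, and the points of RNF2 shRNA2 come from libraries in which RNF2 was not reduced.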

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

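The tests of BMI1 in RNF2 shRNA1, of COMMD3, of RNF2 in groups without an RNF2 hairpin and of S phase genes were chosen only after the results were seen. Each result in this part is a difference between groups in a direct edgeR test, or the median of such differences over a list. The libraries labelled RNF2 shRNA2 differed from RNF2 shRNA1 by log2 1.52 in RNF2, -2.01 in BMI1 and 1.79 in CCL2, and by a median of -1.04 over cholesterol synthesis genes. At 2-fold or more 2074 genes differed between the hairpin groups, 809 between the compounds, 1153 between PRT4165 and the hairpin mean, and 2083 between GW-516 and the hairpin mean. GW-516 exceeded PRT4165 by log2 1.27 in CDKN1A, 1.42 in ATF3 and a median of 1.504 over replication-dependent histones.

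BMI1 was low and RNF2 was not in the libraries labelled RNF2 shRNA2. The tables argue against RNF2 loss lowering BMI1 mRNA to that degree, since with RNF2 reduced by the other hairpin BMI1 differed by log2 -0.13 (95% interval -0.24 to -0.023), against -2.14 here. They also argue against reads shared with COMMD3, the upstream neighbour that forms read-through transcripts with BMI1, which differed by -0.046 (-0.15 to 0.057), and against a swap with Scramble or a compound group, which would leave libraries with low RNF2 there if the hairpin lowers RNF2: 0 of 6 had RNF2 below 50% of the Scramble mean and the lowest stood at 91.2%. What stays open, with no value here that decides, is a hairpin that may target BMI1, a wrong label, or a swap with a sample outside the series, while exchanging the hairpin groups would still leave RNF2 hairpin libraries without low RNF2. Per the file headers these libraries carry the code 20155 where the other hairpin group has sh1, and replicate 2 is marked as 1 lane only; the labels do not say what the code stands for.

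Replication-dependent histones were higher with GW-516 while proliferation genes were lower, although histone mRNA is normally made in S phase. Of the 20 histone genes in the list 14 matched an identifier and 9 were tested, so the pattern covers these 9 alone. A larger share of cells in S phase cannot be excluded. Outside the list of proliferation genes, 27 S phase marker genes had a median log2 of -0.53 against Scramble (95% interval of the median over genes -0.65 to -0.49), and 27 of 27 were lower. S phase marker mRNA was thus not raised. These markers were picked after the proliferation list, which holds replicative helicase genes, was seen to fall, so their fall could be foreseen. The share of cells in each phase was not measured. More RNA without a poly(A) tail in the GW-516 libraries, which may raise histone counts since most histone mRNA has no tail, cannot be told apart: 120 small RNAs without a tail had a median log2 of -0.046, but 6 of them reached 1 CPM, so the test was near the floor. Whether mRNA of the 9 histone genes tested carried a tail was not examined. An effect of the compound on histone mRNA processing or turnover stays open and was not tested.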

How the results depend on the processing

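The summed pairs, the fit without the libraries labelled RNF2 shRNA2 and the thinned counts were chosen only after seeing the data; the other alternatives were planned. RLE size factors, DESeq2, limma-voom, both other filters on low counts, fits of the groups compared alone, an adjusted p of 0.01, thinned counts and the fit without the libraries labelled RNF2 shRNA2 left each count of called genes they were run on within 1.5 times. Replicate numbers share only a number: deviations of same-numbered libraries correlated at -0.21 to 0.038 over 10 pairs of groups, 0 of them over 0.1. With replicate number as a block, counts were 8331 for the hairpin mean, 9992 for RNF2 shRNA1, 7630 for the libraries labelled RNF2 shRNA2, 7517 for PRT4165 and 10124 for GW-516, 131 list tests passed, and of 743 single-gene results CDKN2A between the hairpin groups alone lost its call. Requiring a 2-fold change left, by construction, fewer genes: 797 for the hairpin mean, 1583 for RNF2 shRNA1, 899 for the libraries labelled RNF2 shRNA2, 2074 between hairpin groups, 880 for PRT4165, 1672 for GW-516, 809 between compounds, 1153 and 2083 for PRT4165 and GW-516 against the hairpin mean, 253 shared by both hairpin groups and 143 by the hairpin mean and both compounds. The fit with pairs summed has fewer samples, fewer residual degrees of freedom and a wider spread, whose effects were not told apart. It left 5072, 4902, 4911 and 4555 genes for the hairpin mean, the libraries labelled RNF2 shRNA2, PRT4165 and the compounds against each other, and 1638 and 1435 shared ones. Of 252 list tests 131 passed with the preset correlation, 78 with an estimated one and 213 by fry, which asks another question; why single lists lost their call was not tested.

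Leaving out 1 library at a time, with the lone library left assumed to vary like the other groups, gave 6456 to 8882 genes for the hairpin mean, 8670 to 8708 for RNF2 shRNA1, 6016 to 7791 for the libraries labelled RNF2 shRNA2, 9547 to 10573 between hairpin groups, 5937 to 6812 for PRT4165, 8635 to 8738 for GW-516, 5666 to 6850 between compounds, 7806 to 9270 and 9620 to 11695 for PRT4165 and GW-516 against the hairpin mean, 2393 to 2426 shared by both hairpin groups, 2091 to 2101 shared by the hairpin mean and both compounds, and 128 to 134 passing lists. Direction reversed for values that were not called to begin with: RNF2 with PRT4165 without Scramble replicate 1 (log2 0.050, and -0.055 without Scramble replicate 2), BMI1 with PRT4165 without Scramble replicate 2 (0.014) and without PRT4165 replicate 2 (0.034, and -0.036 without PRT4165 replicate 1), and CCL2 between the compounds without PRT4165 replicate 1 (0.15, and -0.20 without replicate 2); the cause was not tested. Of 743 single-gene results 2 lost their call with DESeq2, 2 with RLE size factors and 11 with pairs summed. Most of these genes were named for a large change or a small adjusted p, so few were likely to lose a call. Over all genes tested, 4896 of 7695 calls for PRT4165 were kept with pairs summed. Whether depth limited genes of a few CPM was not tested by level of expression. Genes below 1 CPM, such as most markers of blood and stromal cells, rest on few counts. In groups of 2 near-identical libraries the p-values may be too small: the common biological coefficient of variation was 0.0340 over all pairs and 0.0511 with pairs summed (7695 to 4911 calls for PRT4165), where the pairs of PRT4165 and of the libraries labelled RNF2 shRNA2 alone give the spread and fewer residual degrees of freedom are left. Whether the near-identical pairs understate the spread between cultures was not tested.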

Other observations

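Luminal and neuroendocrine lineage genes gave no called list in any of the 4 single groups against Scramble. Of 15 androgen receptor targets and luminal genes tested with GW-516, 8 rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.30); the luminal transcription factors HOXB13 and FOXA1 stood at log2 -1.27 and -0.77 (SE 0.029 and 0.037) beside NDRG1, also a hypoxia gene, at 1.91. With PRT4165, 6 rose and 6 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.17), with a median log2 of 0.397, a mean of -0.18 and a test pointing up, with HOXB13 at -1.04, and in RNF2 shRNA1 3 rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.13), with HOXB13 at -0.53. Of 10 neuroendocrine genes in RNF2 shRNA1 3 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.41); ENO2, a neuronal enolase, stood at -1.27, at -0.99 in the libraries labelled RNF2 shRNA2 and at 0.47 and 0.51 with PRT4165 and GW-516.

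Counted by group, 58 of 13104 genes were at least 2-fold apart from all other groups with GW-516, all of them higher, 122 in RNF2 shRNA1 (66 higher, 56 lower), 49 in the libraries labelled RNF2 shRNA2 (3 higher, 46 lower), 9 with PRT4165 and 13 in Scramble.

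Of the tests of upward change with GW-516, that of genes with at least 5 CPM was chosen only after the result was seen. Changes of at least 2-fold with GW-516 were 84.6% upward. Depth, the choice between TMM and RLE, and low counts are argued against as the whole cause. Both normalizations assume that most genes are unchanged, so a shift of most genes was not tested. Of the 1672 calls of at least 2-fold, 282 had a mean of at least 5 CPM. Thinned to the lowest total, 1394 of 1632 such calls were upward, 85.4% (exact binomial interval 83.6% to 87.1%); with RLE size factors 85.5%; and among genes with a mean of at least 5 CPM 84.0% (237 of 282). A compound effect on these genes and a difference in vehicle or culture stay open, since the labels give no vehicle-treated group.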
